A study of Arabidopsis thaliana with 6 samples.

How the data were processed

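RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana grown for 10 days on Murashige and Skoog plates in long days. The labels place 3 libraries in the wild type (Columbia, Col-0) and 3 in the BIC1-YFP line, and call the libraries of each genotype biological replicates. BIC1-YFP names the BIC1 protein joined to yellow fluorescent protein; how the line was made is not given in the sources used here. RNA was extracted with Trizol and sequenced on an Illumina HiSeq instrument, per the labels' protocols.

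TAIR10 and Cufflinks are named in the submitters' processing notes, with no versions. The aligner, the program that counted reads, the scaling between libraries and the test behind the p-values are not given in the sources used here. The table analysed holds 1537 genes. In the authors' deposited table the largest adjusted p is 0.0499 and the smallest absolute log2 fold change is 0.59, so it is a list of genes the authors had already selected as different between the genotypes. Genes outside that selection are not analysed here. A gene absent from the table is therefore not shown to be unchanged, and no test against the rest of the genome was possible. The design text names a fold change limit of 0.5 without saying on which scale.

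The value per gene and library that the authors deposited is a normalized signal of read abundance, written with decimals. Of the values under 15, those within 0.05 of a whole number made up 95.9% in wild-type replicate 1 and 100% in BIC1-YFP replicate 1, and 6.1% to 17.4% in the other libraries. A division by the length of each gene would not leave whole numbers in 2 libraries, so the values are taken not to be FPKM although Cufflinks is named. The other 4 libraries are taken to be in the same unit because they are in the same table. Whole reads could not be taken back from the values, so no test for read counts was used. The total number of reads per library is unknown. The listed genes alone sum to between 1801802 and 2064622 normalized units per library, which is not a depth. The deposited table also gives a mean signal per genotype, which equals the mean of the 3 libraries, a log2 fold change, a p-value and an adjusted p-value. The deposited log2 fold changes fall in 2 groups when set against the ratio of the deposited means, as described among the closing observations, so every fold given in the results was recomputed from the library values.

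The design fixed before the data were examined assumed FPKM or read counts. Because the values are neither, the test planned for FPKM was used on the normalized abundance. Genes with a value of at least 1 in 3 or more of the 6 libraries were kept (1531 of 1537), values were put on the scale log2(value + 1), and the genotypes were compared with limma 3.58.1 in R 4.3.3, with a trend of variance on abundance and no covariate. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene was called at an adjusted p under 0.05. The listed genes were chosen by the authors for differing in these same libraries. The adjustment over them is therefore lenient, the variance prior comes from selected genes, and a call is not independent evidence of the authors' selection. A log2 fold change on this scale understates the change of genes with low values. Folds written as "x-fold" are ratios of the mean abundances, errors after ± are standard deviations over 3 libraries, and SE is limma's standard error. Tested on simulated data with 200 changed genes among 1537 and a dispersion of 0.02, the procedure recovered 49.8% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 98% of those changed 4-fold, with 3.36% false calls. Most simulated genes were unchanged, whereas the listed genes were selected as different. Some listed genes also vary far more, such as HSFA2 at 79.1 ± 78.1 units in the wild type. These rates therefore check the procedure and do not carry over to the real calls.

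A total of 28 gene lists, holding 419 genes, were written before the data were examined. Of these genes, 122 are in the table and 4 lists have no member there. For the 16 lists with at least 3 tested members, camera (in limma) asked whether the members moved further in 1 direction than the other listed genes, with a preset correlation between genes of 0.01 and again with a correlation estimated per list. Fisher's exact test (two-sided) compared the split into higher and lower genes with that of the other listed genes. It treats genes as independent. The estimated correlation between members was 0.45 in the flavonoid list and 0.22 in the SAUR list, so its p-values overstate the evidence there. The fry test (in limma) asked whether members moved, on balance, 1 way, which the authors' selection already favours; it passed for 11 lists and is not used further. The genes named are BIC1 and BIC2, the 10 called genes with the largest fold change in each direction whose genotypes do not overlap and whose higher genotype has a mean of at least 100 units, and up to 3 called members per direction of each list, or the member with the smallest p where none was called. Any member could be named from the lists on brassinosteroid, SAUR, cell wall, PIF and photoreceptor genes. The limit of 100 had been written for reads and was applied to normalized units.

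Gene symbols come from the TAIR10.1 RefSeq annotation and the prewritten lists. The identifiers of 1517 genes matched it; the 20 others are chloroplast genes. Since that build differs in name from TAIR10, no coordinates are given. Reads from the endogenous BIC1 gene and from the transgene cannot be separated in these values. Near-identical copies (SAUR19 to SAUR24, SAUR61 to SAUR68, the LHCB1 genes and the RBCS genes) may share reads, so the split between copies is uncertain, and whether the counting used strand is not given in the sources used here.

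The alternatives tried were pseudocounts of 0.1 and 5, no filter and a stricter filter on low values, scaling by the median ratio of the listed genes, limma without the trend, the authors' deposited adjusted p, minimum log2 fold changes of 0.5 and 1, the replicate number as a block, an estimated correlation in the list test, and each library left out in turn. Added after seeing the data were an adjustment over 21574 tests, the genes with a deposited fold change below 1.2 times the recomputed one, and replicate 3 of both genotypes left out. The number 21574 is the smallest that the deposited p-values and adjusted p-values of the genes below that 1.2 limit allow. The remaining genes were not used for it. Figures were drawn with matplotlib 3.10.9.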

Results

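The data are transcript abundances in 10-day-old Arabidopsis seedlings of the wild type and of a line carrying BIC1-YFP, with 3 biological replicates of each. BIC1 is a small nuclear protein known as an inhibitor of the blue-light receptor cryptochrome, and the comparison addresses its role as a coactivator in brassinosteroid signalling and growth. Abundances are normalized units as the authors deposited them, for the 1537 genes that the authors selected as differing between the genotypes. The depth of the libraries is unknown.

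BIC1 (AT3G52740) stood at 340.0 ± 75.4 units in the wild type and at 17579 ± 3808 in BIC1-YFP (SD, n = 3), a 51.7-fold higher mean. Its log2 fold change was 5.69 (SE 0.22, limma, adjusted p = 4.6e-05), and the lowest BIC1-YFP library (14597) lay far above the highest wild-type library (409). Its paralog BIC2 (AT3G44450) went the other way, from 463 ± 221 to 171 ± 58.9 units, with a log2 fold change of -1.35 (SE 0.46, limma, adjusted p = 0.034). The BIC2 libraries of the genotypes overlapped. Its call was lost without wild-type replicate 1, wild-type replicate 2, BIC1-YFP replicate 2 or BIC1-YFP replicate 3, with limma adjusted p of 0.1, 0.094, 0.078 and 0.094.

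Of the 1537 genes, 809 had a higher mean in BIC1-YFP and 728 a lower one. Of the 1531 tested, limma called 1173, of which 575 rose and 598 fell, and 507 of these changed by at least 1 on the log2 scale. Counts of list members that rose or fell, given below, are likewise counts of called genes. The libraries of the genotypes did not overlap for 1164 genes (76.0%), where chance alone gives 10% of unselected genes. The first principal component, with 67.5% of the variance among these selected genes, separated the genotypes; wild-type replicate 3 (-14.2) lay closer to the BIC1-YFP libraries than wild-type replicates 1 (-29.6) and 2 (-28.2). The number of calls was 623 without wild-type replicate 1, 625 without wild-type replicate 2, 469 without BIC1-YFP replicate 2 and 715 without BIC1-YFP replicate 3. It was 1218 without wild-type replicate 3 and 983 without BIC1-YFP replicate 1. Over the 21574 tests that the deposited p-values of 645 of the genes imply at the least, 50 genes were called, and most lists below kept no call. That adjustment was put on limma's p-values and counts every gene outside the selection as a test that does not pass. The authors' own adjusted p was under 0.05 for all 1537 genes, which their selection had fixed.

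**Figure D1:**
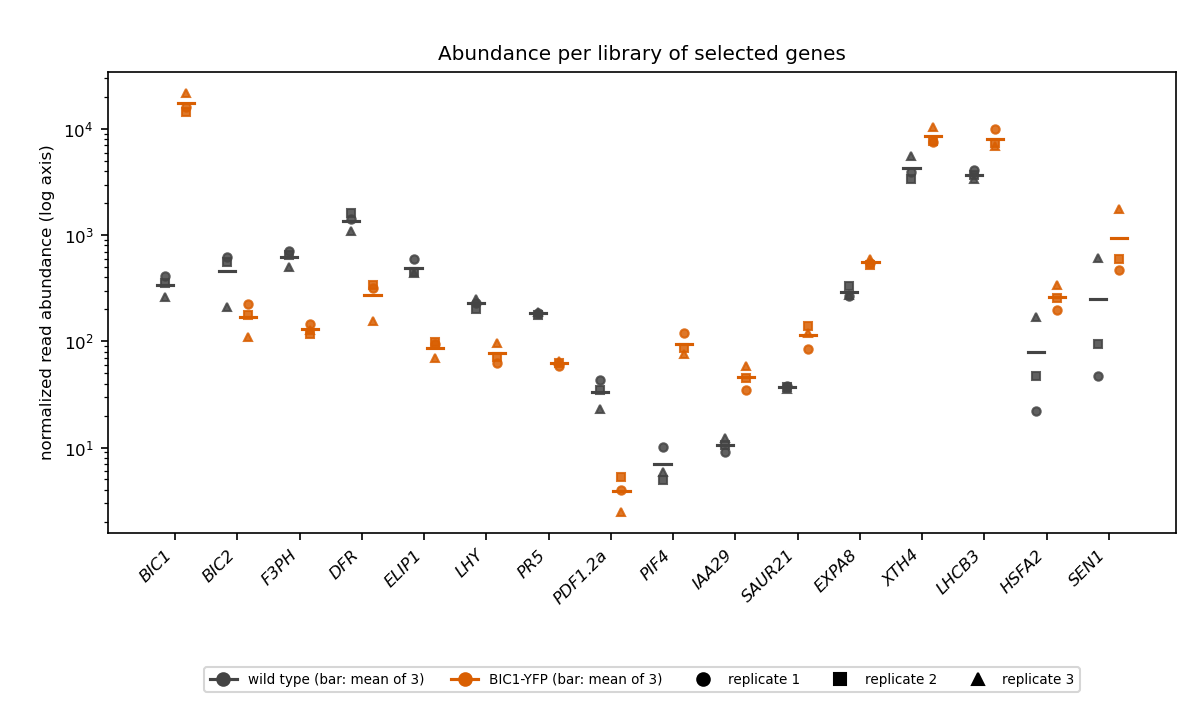
Normalized read abundance (log axis) of 16 genes in each of the 6 libraries; grey symbols are wild type, orange symbols BIC1-YFP, the symbol shape gives the replicate and the bar the mean of 3 libraries. BIC1 lies 51.7-fold higher in BIC1-YFP, the flavonoid gene DFR 5.05-fold lower and PIF4 13.6-fold higher, while the libraries of BIC2 and SEN1 overlap between the genotypes.

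Genes of flavonoid and anthocyanin synthesis fell together. Of the 16 genes in that list, 15 were among the listed genes, all lower in BIC1-YFP and all called, with 15 also adjusted over the list alone and 5 over the 21574 tests; MYB111 was not in the table. DFR (AT5G42800), which reduces dihydroflavonols toward anthocyanins, fell from 1369 ± 259 to 271 ± 100.1 units (5.05-fold lower, log2 fold change -2.39, SE 0.32, limma, adjusted p = 0.0036). The flavonoid hydroxylase gene F3PH (AT5G07990) fell from 619 ± 104 to 130.1 ± 14.5 units (4.76-fold lower), and the anthocyanin acyltransferase gene 5MAT (AT3G29590) from 254 ± 42.4 to 55.4 ± 24.8 units (4.59-fold lower). The median log2 fold change of the list was -1.90. Camera with the preset correlation separated it from the other listed genes (adjusted p = 2.1e-06), but not with an estimated correlation (adjusted p = 0.34 with an estimated correlation), and Fisher's exact test on the direction gave an adjusted p of 1.0e-04.

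SAUR genes, small auxin-induced transcripts linked to cell expansion, rose. Of 23 in the list, 18 were listed, all higher in BIC1-YFP, and 14 were called, also 14 adjusted over the list alone but 0 over the 21574 tests. Most of the listed and of the called members are among the near-identical copies SAUR19 to SAUR24 and SAUR61 to SAUR68. Those may share reads, so the counts are not of independent genes. SAUR21 (AT5G18030) rose from 37.0 ± 1.35 to 115 ± 27.4 units (3.09-fold, log2 fold change 1.58, SE 0.25, limma, adjusted p = 0.0050), SAUR19 (AT5G18010) from 4.11 ± 2.61 to 21.5 ± 5.94 and SAUR10 (AT2G18010) from 2.63 ± 0.344 to 12.4 ± 0.536. SAUR61 (AT1G29420) and SAUR68 (AT1G29490) were near 0 in the wild type (0.288 and 0.624) and at 9.14 ± 4.19 and 7.69 ± 0.818 in BIC1-YFP. SAUR50 (AT4G34760), at 537 ± 184 and 913 ± 433 units, did not pass (limma, adjusted p = 0.13). The list had a median log2 fold change of 1.14 and a camera adjusted p of 9.9e-04 (adjusted p = 0.34 with an estimated correlation), and Fisher's exact test on the direction gave 1.0e-04. Its calls numbered 8 without wild-type replicate 1, 8 without wild-type replicate 2, 6 without BIC1-YFP replicate 2 and 6 without BIC1-YFP replicate 3. They numbered 17 without wild-type replicate 3 and 15 without BIC1-YFP replicate 1.

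Among genes known to be induced by brassinosteroid, 7 of 20 were listed, and 5 rose while 1 fell (6 adjusted over the list alone). Some of these are counted in other lists too: EXPA8 among the cell wall genes, IAA19 among the auxin genes and SAUR15 among the SAUR genes. IAA29 is in both the auxin and the PIF list. These lists are therefore not separate evidence. EXPA8 (AT2G40610), a cell wall expansin, rose from 289.7 ± 35.6 to 559 ± 35.4 units (1.93-fold) and the auxin-response gene IAA19 (AT3G15540) from 65.5 ± 12.1 to 120 ± 15 (1.83-fold). The growth-promoting helix-loop-helix genes PRE1 (AT5G39860) and PRE5 (AT3G28857) rose 4.82-fold and 3.80-fold from low levels, while PRE4 (AT3G47710) fell from 16.2 ± 4.65 to 5.6 ± 3.31 units. PRE2 (AT5G15160), at 64.3 ± 10.6 and 102 ± 31.4 units, did not pass. Without BIC1-YFP replicate 2 only 1 member was called higher and none lower. Without BIC1-YFP replicate 1, 3 were called higher and 1 lower. Without each of the other libraries 4 or 5 were called higher and none lower. The direction of every listed member stayed the same. The list did not stand apart from the other listed genes (camera, adjusted p = 0.12). None of the 13 genes of brassinosteroid metabolism was in the table. Of 16 brassinosteroid signalling genes only BSU1 (AT1G03445), a phosphatase, was listed; it fell from 25.8 ± 2.39 to 10.6 ± 1.53 units (2.43-fold lower, limma, adjusted p = 0.015; 1 call adjusted over the list alone).

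PIF4 (AT2G43010), a transcription factor of shade and warmth growth, rose from 6.97 ± 2.71 to 94.4 ± 23.8 units (13.6-fold, log2 fold change 3.61, SE 0.34, limma, adjusted p = 0.0015), and PIF5 (AT3G59060) rose from 147 ± 45.6 to 335 ± 50.6 (2.27-fold). With IAA29 (AT4G32280, 4.36-fold) and PAR1 (AT2G42870, 2.80-fold) they were the 4 members of the 18 PIF and shade-induced genes that were listed, and each was called (4 adjusted over the list alone; camera, adjusted p = 0.056). PAR1 lost its call without wild-type replicate 1, wild-type replicate 2, BIC1-YFP replicate 2 or BIC1-YFP replicate 3 (limma, adjusted p from 0.057 to 0.063). Of 24 auxin genes, 6 were listed as higher and 4 rose (3 adjusted over the list alone), with 1 call without BIC1-YFP replicate 2. Of 32 cell wall genes, 5 rose and 1 fell (6 adjusted over the list alone): the expansin EXPA3 (AT2G37640) rose from 1043 ± 38.3 to 2376 ± 154 units (2.28-fold), the xyloglucan enzyme gene XTH4 (AT2G06850) rose 2.01-fold and XTH31 (AT3G44990) fell 1.73-fold. Without BIC1-YFP replicate 2, 3 cell wall genes were called higher. Of 13 gibberellin genes, 4 were listed as higher and 3 rose (4 adjusted over the list alone), led by GASA6 (AT1G74670), 1844 ± 492 against 3878 ± 891 units; 1 was called without BIC1-YFP replicate 2. Camera gave adjusted p of 0.097 for each of these 3 lists. None of the 11 photoreceptor and light-signalling genes, 11 cytokinin response genes and 7 cell cycle genes was listed.

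**Figure D2:**
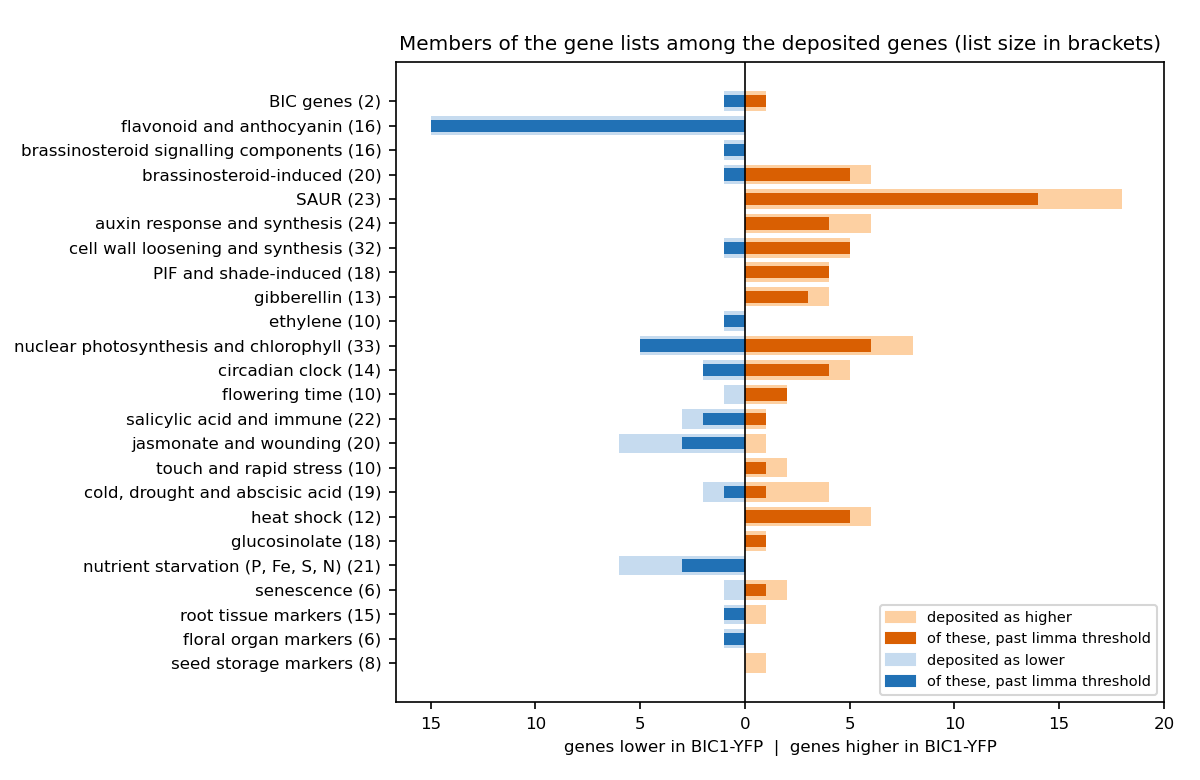
Members of the gene lists that are in the deposited table, split into those lower (left) and higher (right) in BIC1-YFP; pale bars count listed genes, dark bars those past the limma threshold, and list sizes are in brackets. The flavonoid list has 15 lower and 0 higher members and the SAUR list 18 higher and 0 lower.

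Photosynthesis genes moved in both directions. Of 33 nuclear genes, 13 were listed, of which 6 rose and 5 fell (11 adjusted over the list alone), and the median log2 fold change was 0.58 against a mean of 0.05 (camera, adjusted p = 0.65). The antenna genes LHCB3 (AT5G54270) and LHCA4 (AT3G47470) rose 2.17-fold and 1.74-fold. The early light-induced genes ELIP1 (AT3G22840) and ELIP2 (AT4G14690), linked to protection from strong light, fell 5.69-fold and 4.25-fold, and the Rubisco subunit gene RBCS3B (AT5G38410) fell 1.57-fold. All 20 listed chloroplast-encoded genes were lower in BIC1-YFP and 8 were called, with 1 call without wild-type replicate 2. Of 14 clock genes, 4 rose and 2 fell (6 adjusted over the list alone): the morning gene LHY (AT1G01060) fell 2.95-fold and PRR7 (AT5G02810) rose from 24.7 ± 3.7 to 71.7 ± 33.9. Of these clock genes, 2 were called higher without wild-type replicate 1, wild-type replicate 2, BIC1-YFP replicate 2 or BIC1-YFP replicate 3. Only 1 was called lower without wild-type replicate 1, wild-type replicate 2, BIC1-YFP replicate 1 or BIC1-YFP replicate 2. Of 10 flowering genes, SPL3 (AT2G33810) rose 2.52-fold and FLC (AT5G10140) 1.95-fold (2 adjusted over the list alone; neither was called without BIC1-YFP replicate 2).

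Among defence genes, PR5 (AT1G75040), a salicylic acid marker, fell from 183 ± 6.11 to 62.4 ± 3.07 units (2.93-fold lower) and FRK1 (AT2G19190) fell 3.23-fold, whereas ALD1 (AT2G13810), which makes an immune signal, rose from 1.63 ± 0.383 to 11.7 ± 2.04; these were the calls among 22 salicylic acid and immune genes (4 adjusted over the list alone). Of 20 jasmonate genes, 7 were listed and 3 fell (3 adjusted over the list alone), among them the defensin PDF1.2a (AT5G44420), from 33.6 ± 10.1 to 3.92 ± 1.4 units, and AOC1 (AT3G25760), an enzyme of jasmonate synthesis, 1.61-fold lower. The third, AOS (AT5G42650), lost its call without wild-type replicate 1 or 2 or BIC1-YFP replicate 2 or 3 (limma, adjusted p from 0.073 to 0.086). Jasmonate genes called lower numbered 5 without wild-type replicate 3 and 2 without wild-type replicate 2. Of 12 heat shock genes, 6 were listed as higher and 5 rose (6 adjusted over the list alone), led by the regulator HSFA2 (AT2G26150) at 79.1 ± 78.1 and 263 ± 70.4 units. Wild-type replicate 3 (168) was the highest wild-type library for HSFA2, and the list kept 0 calls without wild-type replicate 1, wild-type replicate 2 or BIC1-YFP replicate 2, and 1 without BIC1-YFP replicate 3.

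The remaining lists had few calls. In the nutrient list of 21 genes, 6 were listed as lower and 3 fell (2 adjusted over the list alone), led by the sulfur-response gene SDI1 (AT5G48850, 2.96-fold lower). Only 1 nutrient gene was called lower without wild-type replicate 2 or BIC1-YFP replicate 2. Of 19 cold, drought and abscisic acid genes, RD29B (AT5G52300) rose 2.50-fold and KIN1 (AT5G15960) fell 2.54-fold (2 adjusted over the list alone). RD29B lost its call without BIC1-YFP replicate 2 (limma, adjusted p = 0.060) and KIN1 without wild-type replicate 1 (0.057) or 2 (0.060). Single calls were ERF104 (AT5G61600) of 10 touch genes, CYP79B3 (AT2G22330) of 18 glucosinolate genes and SEN1 (AT4G35770, 251 ± 313 against 947 ± 723 units) of 6 senescence genes, all higher. ACO1 (AT2G19590) of 10 ethylene genes, the root gene PRP3 (AT3G62680) of 15 and the floral gene SEP1 (AT5G15800) of 6 were lower. The counts adjusted over the list alone were 1 for the touch, glucosinolate, ethylene and floral lists, 2 for the root list and 0 for the senescence list. Of 8 seed storage genes, CRA1 (AT5G44120) was listed and did not pass; it stood at 83.6 units in BIC1-YFP replicate 2 and at 0.219 to 6.94 in the other libraries. Of the single calls, SEP1 held without any 1 library, and the others were lost without at least 1 of the BIC1-YFP libraries (limma, adjusted p between 0.051 and 0.127). ERF104, SEN1 and PRP3 were also lost without wild-type replicate 1 or wild-type replicate 2 (limma, adjusted p from 0.0577 to 0.126).

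The genes in this paragraph were ranked among called genes whose libraries do not overlap between the genotypes and whose mean is at least 100 units in the higher genotype, so larger folds among weaker or more variable genes are left out. Within that limit and outside the lists, the largest rises after BIC1 were AT1G73120 (no description in the table), from 551 ± 120.2 to 5291 ± 1996 units (9.59-fold), P1R3 (AT3G29370, 7.36-fold), the auxin glucosyltransferase gene UGT74E2 (AT1G05680, 6.25-fold) and the cytochrome P450 gene CYP81D11 (AT3G28740), from 325 ± 102 to 1784 ± 209 units (5.48-fold). Within the same limit, the largest falls were the defensin PDF1.3 (AT2G26010), from 157 ± 22.0 to 6.53 ± 5.28 units (24.0-fold lower), the glycosyltransferase gene AT2G22590 (11.9-fold lower), the beta-amylase gene BAM6 (AT2G32290, 6.92-fold lower) and the receptor kinase gene AT1G29720 (6.28-fold lower). The limma adjusted p of these 8 genes lay between 0.0014 and 0.0070. Of the 85 named genes that were called, 47 stayed past the threshold with each of the 6 libraries left out in turn and 38 did not, and none changed sign.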

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

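The adjustment over 21574 tests, the table restricted to genes with the lower deposited fold changes, and replicate 3 of both genotypes left out were chosen after seeing the data; the other alternatives were planned. The 1173 calls (575 higher, 598 lower) stayed within 1.5 times under both pseudocounts, both filters, median-ratio scaling, limma without trend and replicate 3 of both genotypes left out. The authors' adjusted p called all 1537 genes, which their selection had fixed. A minimum log2 fold change of 0.5 left all 1173, but the smallest absolute log2 ratio of means among the listed genes was already 0.525. Neither count bears on how stable the calls are. A minimum of 1 left 507 (258 higher, 249 lower), by construction. The restriction to lower deposited fold changes tested 640 genes and left 640 (321 and 319), of which 626 were called in the main setting. Adjustment over 21574 tests left 50 (25 and 25). Leaving out 1 library gave 469 to 1218 calls, 213 to 620 higher and 256 to 598 lower; the loss of 1 library lowers power, and why the libraries differ in it was not tested. Median-ratio scaling shifted log2 fold changes by -0.07 and the higher share from 49% to 47%. BIC1 stayed called at a log2 fold change of 5.34 to 5.84 in 19 alternatives. Lists called by camera were 2 in the main setting, 0 with an estimated correlation, 6 with the replicate block, 4 with replicate 3 of both genotypes left out and 2 to 4 with 1 library left out; the cause was not tested. No named gene changed direction, but the median log2 fold change of the 2 listed root genes went from 0.07 to below 0 in 3 alternatives (lowest -0.11). The restriction kept only 1 of these 2 genes and 2 of the 6 listed cold, drought and abscisic acid genes, so its medians (-0.82 and -0.10) are of other members than the main ones (0.07 and 1.05); 69 named genes lost their call over 21574 tests, 36 without BIC1-YFP replicate 2 and 26 at a minimum of 1. With the replicate block, 1445 genes were called, including all 1173. Same-numbered libraries correlated in their deviations at 0.42, 0.04 and 0.44. Wild-type replicate 1 and BIC1-YFP replicate 3 correlated at -0.43, and wild-type replicate 3 and BIC1-YFP replicate 1 at -0.4. Deviations were taken from the genotype mean, so those of the 3 libraries of a genotype cancel for each gene. The negative values therefore largely follow from the positive ones and are not further evidence. What they show together is 1 contrast, replicate 1 against replicate 3, that went the same way in both genotypes. Correlations that involve a replicate 2 lay between -0.12 and 0.09 and decide nothing. A factor shared by same-numbered libraries therefore stays possible, and the main test leaves its variation in the residual. Not run were the alternatives for read counts, for 1 value per genotype and for random lists, which these values do not allow or need. Depth is unknown, so no counting limit can be given for low genes.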

Other observations

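The tests on gene families, other splits, deposited fold changes, chloroplast genes and the gap among wild-type libraries were chosen after the results they concern had been seen; the heat shock list and leaving out 1 library were planned. Grouped by the deposited descriptions, 30 gene families had at least 5 members in the table, and Fisher's exact test on direction passed for 2 of them. That test treats members as independent, so its p-values are too small where copies share reads or vary together. The SAUR-like family had 31 of 32 members higher in BIC1-YFP (adjusted p = 1.4e-06), 23 of them called. It overlaps the prewritten SAUR list; of the 14 members outside that list 13 were higher and 9 were called, all higher (Fisher's exact p = 0.0020), among them SAUR26 to SAUR29. Genes described as integrase-type DNA-binding proteins, a label that only part of the AP2/ERF genes in the table carry, were higher in 11 of 11 (adjusted p = 0.016). Of these, 2 were too low to be tested, 4 of the other 9 were called by limma, and BIC1-YFP replicate 3 was the highest of its genotype in 8 of the 11. The called ones included DREB2C (AT2G40340), a dehydration-response regulator, at 10.7 ± 5.72 and 31.4 ± 5.98 units, DREB19 (AT2G38340) at 3.94 ± 1.70 and 14.3 ± 0.465, and ABR1 (AT5G64750) at 7.16 ± 3.36 and 18.4 ± 3.94 (SD, 3 libraries each). TIR-NBS-LRR resistance genes were lower in 7 of 7 (adjusted p = 0.053) and UDP-glycosyltransferases in 13 of 16 (adjusted p = 0.072), which miss the threshold.

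With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1173 calls and the highest of the others 33; 1 of the 10 splits gave as many as the real one, and the genes had been selected for the real split.

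The deposited log2 fold changes fall in 2 groups. In 892 genes the deposited value is more than 1.2 times the log2 ratio of the means, with a median of 1.445 times it (364 genes above 100 units in every library), and in 645 genes it is lower, with a median of 0.877 in the 314 of them above 100 units. The second group has no single scale; over all 645 genes the quartiles were 0.681 and 0.880 and the range 0.0944 to 1.02. A scaling between libraries would raise the ratio in 1 direction only, whereas the first group holds 484 higher and 408 lower genes (45.7% in the smaller direction), which argues against it. A log2 value divided again by the natural log of 2 stays open. In 5 bins of fold size the median ratio lay up to 0.0208 from 1/ln 2 over all 892 genes, farthest in the bin of largest folds (1.42, quartiles 1.39 and 1.44), and up to 0.00311 over the 598 genes with at least 20 units in every library. Limma called 61.4% of the first group and 97.8% of the second, and why the table holds both stays open.

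All 20 listed chloroplast-encoded genes were lower in BIC1-YFP, at a median log2 fold change of -1.25, and 8 were called. Without wild-type replicate 2, the highest library, the median was -0.65 and 1 was called; all 20 stayed below 0, but wild-type replicate 3 then lay below BIC1-YFP replicate 1, so 1 library with more chloroplast RNA and a genotype effect cannot be told apart. The gap among wild-type libraries was 1.75 times that between the genotypes, as would be seen if chloroplast RNA was captured to a different extent from library to library. That gap alone does not show what made the libraries differ. A biological effect of BIC1-YFP stays open.

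The 6 listed heat shock genes were higher in BIC1-YFP, with a median log2 fold change of 1.37, and 5 were called. Wild-type replicate 3 was the highest wild-type library in 6 of 6 and BIC1-YFP replicate 3 the highest of its genotype in 5 of 6. The gap among wild-type libraries was 1.1 times the gap between genotypes, as would be seen if harvest or handling differed from library to library. That gap alone does not show what made the libraries differ. Without wild-type replicate 3 all 6 were called, at a median of 1.76, so the high values of that library narrowed the difference between the genotypes. An effect of the genotype also stays open.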
